A study of Danio rerio with 12 samples.

How the data were processed

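RNA was taken from whole zebrafish larvae of the Tg(fli:EGFP) line, in which a fluorescent protein marks blood vessels, at 120 hours after fertilization. Per the labels' protocols, 20 embryos were pooled in each of 3 conditions, 1 poly(A) RNA library was made from each pool, and each library was sequenced on 4 lanes of a NextSeq instrument. The 12 GEO samples are therefore 3 libraries (control, IC and Dx-IONP) on 4 lanes each, and the 4 GEO samples of a group are lanes of 1 library, not replicates. Dx-IONP names dextran-coated iron oxide nanoparticles. In the library names the Dx-IONP library has a number apart from the consecutive ones of control and IC, while all 3 share the first part of the name and have consecutive sample numbers. Whether it was prepared apart was not given in the sources used here. The labels do not spell out IC. The protocol lists control, iron and nanoparticle conditions, so by elimination IC is the iron group, and nothing further is known of it here. The dose and duration of exposure were not given in the sources used here.

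The deposited table holds unnormalized estimated counts per gene and lane, written as whole numbers by the authors. Per the submitters' processing notes, FastQC, Salmon 1.6.0, R 4.1.2, DESeq2 1.34.0 and the genome build GRCz11 were used. How transcript estimates were summed to genes, whether strand was used and whether rows were filtered were not given in the sources used here. Salmon assigns reads shared by similar transcripts by likelihood, so the estimated counts of recent gene duplicates, which are common in zebrafish, can be split unevenly. The deposited estimated counts were used as they stand, with no further rounding. The table has 19983 rows, of which 494 were 0 in every lane. A name table paired 19182 of the identifiers with symbols, many in the human style (OPN1SW, MYH7), and 2450 symbols were shared by several rows. Synonyms came from a RefSeq gene table of the assembly GRCz12tu, which was used for names only. No coordinates are given, because no genome of the build GRCz11 was used here.

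Lane totals were 20606371 to 21329490 reads for control, 11847840 to 12239616 for IC and 13569110 to 14063966 for Dx-IONP. Before summing, the lanes were compared over genes with a mean of at least 10 reads per lane. The median chi-square per degree of freedom was 0.97 in control, 0.93 in IC and 0.98 in Dx-IONP, against 0.79 from sampling noise alone. The mean was 2.04, 1.79 and 2.43. The typical gene thus varied slightly more between lanes than sampling noise, and some genes far more. The coefficient of variation between lanes was 0.04 over all genes (edgeR's common dispersion). The lanes were summed, which gave 84043873, 48283541 and 55381504 reads per library and n = 1 library per condition.

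TMM factors for the 3 libraries (edgeR 4.0.16 in R 4.3.3) were 1.11 for control, 1.05 for IC and 0.86 for Dx-IONP. Genes with at least 1 CPM in at least 1 library were kept, which left 16807. CPM values are the summed reads scaled by the TMM library size. Log2 folds were computed with a prior count of 2, scaled to each library. With 1 library per condition no test between conditions was made. A gene was counted where it was at least 2-fold apart and the exact 95% interval of its ratio (Clopper-Pearson on the conditional binomial) excluded a ratio of 1. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and pools of larvae differ. Intervals printed beside log2 folds are of this kind. A fold against 0 reads was computed against a floor of 3 counts in that library and is a lower bound. At these depths 0 reads allow up to 0.036 CPM of all reads in control, 0.062 in IC and 0.054 in Dx-IONP.

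Gene lists (30) and the rule for named genes were fixed before the data were examined. The lists hold 1138 entries (1112 different members), of which 811 entries were in the table, matched by symbol (663), synonym (51) or name without the paralog letter (97). Each list was described by the median log2 fold of its measured members, the order-statistic 95% interval of that median over members, and the percentile of the median among 10000 random lists of the same size. Random members were drawn from the 50 genes on either side in mean expression. A list was said to stand apart below percentile 2.5 or above 97.5, which describes these libraries and is no test of a condition. The genes named were the 10 highest and 10 lowest log2 folds per comparison among genes with at least 10 CPM in the higher library, the same direction in all 4 lanes and a proper symbol. To these were added 5 genes that set Dx-IONP apart from both other libraries, up to 4 genes per list past the rule, and 23 fixed readouts, 18 of which were in the table. Other genes are said to have been chosen afterwards where they appear. Not every gene that this rule selected is printed in the text.

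The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. They were tested on simulated data: Poisson counts for the real genes with 200 genes changed. For Dx-IONP against control, 100 of 100 genes changed 3-fold and 0 of 100 changed 1.5-fold passed the rule, and 1 of 16085 unchanged genes did. For IC against control the numbers were 100 of 100, 0 of 100 and 0 of 16082, and for Dx-IONP against IC 99 of 100, 1 of 100 and 1 of 16102. Simulated intervals held the true ratio for 95.5%, 95.3% and 95.3% of genes in that order.

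Alternatives were other scalings (DESeq2 1.42.0 size factors, total reads, upper quartile, and TMM or total reads without the globin, lens, pancreas and mitochondrially encoded lists), leaving out each lane, prior counts of 0.5 and 10, no filter or at least 10 CPM, and folds of 1.5 and 4. The lanes were also entered as if they were samples in edgeR's quasi-likelihood test, with and without the lane as a block, and in DESeq2. Such tests compare these libraries beyond lane noise and not the conditions.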

Results

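Gene expression was measured by RNA sequencing in whole zebrafish larvae of 3 conditions: control larvae, larvae labelled IC (by elimination the iron group) and larvae exposed to dextran-coated iron oxide nanoparticles (Dx-IONP). The study's design text gives developmental toxicity and effects on the heart as its subject. Each condition was 1 library from a pool of 20 embryos at 120 hours after fertilization, with 84043873 reads for control, 48283541 for IC and 55381504 for Dx-IONP. The 4 GEO samples of each condition are lanes of that library. No difference below has a replicate check, so values are given as higher or lower in a library.

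The comparison of Dx-IONP with control asked what differed in larvae exposed to the coated particles. Genes of the eye, exocrine pancreas and nervous system were far lower in the Dx-IONP library, while embryonic globin and haem synthesis genes, most replication histone genes and the keratin gene krt4 were higher. The short-wavelength cone opsin OPN1SW (ENSDARG00000045677) stood at 4.23 CPM against 2484 in control, a log2 fold of -9.19 (95% counting interval -9.40 to -9.00). The embryonic beta globin hbbe3 (ENSDARG00000038147) stood at 727.9 CPM against 3.49, a log2 fold of 7.69 (7.55 to 7.87). The keratin krt4 was the most abundant gene of the Dx-IONP library, with 8.35% of its reads, and had 97330 CPM against 14900. Of 16807 genes, 7575 (45.1%) were at least 2-fold apart with a counting interval that excluded equality, 3505 higher and 4070 lower in Dx-IONP. Scaled to total reads alone, the split was 2301 higher and 5334 lower, with the median gene at -0.35 on the log2 scale.

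Among the 30 lists, 11 stood apart from matched random lists in this comparison. All 28 measured photoreceptor genes were lower in Dx-IONP, with a median log2 fold of -5.18 (interval over members -7.25 to -4.21, percentile 0). The cone transducin gene GNGT2 was at -8.95, the green opsin opn1mw1 at -8.84 and a gene for the outer segment protein peripherin, PRPH2, at -8.44. Exocrine pancreas genes were lower for 12 of 14 members and higher for 1 (median -4.28, -6.51 to -1.69), among them the chymotrypsinogen gene ctrb.1 at -8.25 (-14.87 to -7.08) and the trypsin-like prss59.2 at -7.57. Neuronal and glial markers were lower for 23 of 26 and higher for 1 (median -2.999, -3.97 to -1.67), with the synaptic vesicle gene SV2A at -4.63 and the growth cone gene gap43 at -5.05. Lens genes were lower for 37 of 45 and higher for 0 (median -1.72). Intestine markers were lower for 9 of 18 and higher for 3 (median -1.29, -4.47 to 0.51), with the brush border gene VIL1 at -5.97, and no longer stood apart with no filter (percentile 3.29) or at 10 CPM (7.02). Mitochondrially encoded genes were lower for 9 of 13 (median -1.82, -3.16 to 0.04), while MT-ND6 was higher at 2.46. Liver markers were lower for 9 of 28 and higher for 2 and did not stand apart (median -0.34, percentile 4.35). Their lowest members were fabp10a, a hepatocyte fatty acid binding protein gene, at -8.01, GC at -7.485 and uox at -6.34. The tryptophan-degrading enzyme gene TDO2, which is not on that list, was at -8.23.

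Higher in the Dx-IONP library were haem synthesis and embryonic globin genes, 16 of 21 members with 0 lower (median 2.54-fold, log2 interval 1.02 to 1.85, percentile 100). They included alas2, the erythroid enzyme at the start of haem synthesis, at 2.82. Inflammation and acute phase genes were higher for 17 of 29 and lower for 5 (median 1.19, -0.03 to 1.62), with NOS2 at 4.71, the matrix protease MMP9 at 1.91 and the cytokine il1b at 2.46. The lower members included the complement genes c3a.2 at -6.54 (-10.39 to -5.48) and c3a.3 at -4.60, which liver commonly makes. Cell cycle genes were higher for 9 of 27 and lower for 0 (median 0.89, 0.39 to 1.11), with the replication genes FEN1 at 1.38 and MCM2 at 1.32. Epidermis, cartilage and matrix genes were higher for 14 of 32 and lower for 3 (median 0.74, 0.19 to 1.40). The iron list was higher for 12 of 25 members and lower for 3 (median 0.84, 0.37 to 1.95). Its largest value was that of ftr83, a finTRIM family gene and no iron gene that the fixed list holds by mistake, with 1023 reads in Dx-IONP and 0 in both other libraries. Without ftr83, left out after its values were seen, 11 of 24 were higher and 3 lower, and the list still stood apart (median 0.78, 0.08 to 1.95). In that list the transferrin receptor gene tfr1a (ENSDARG00000101322) was at 3.28 (3.18 to 3.40), with 82.3 CPM against 8.43. Its paralog tfr1b differed little, with 42.0 CPM against 32.4. SLC25A37, the mitochondrial iron importer of red cells, was at 4.46. The hepcidin gene hamp (ENSDARG00000102175), a liver hormone that limits iron release, was at -4.45 (-5.06 to -4.01). The ferritin gene fth1a was at -0.29, and a second ferritin gene, FTH1 (ENSDARG00000007975), at -2.01 (-2.17 to -1.86).

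The largest log2 folds in either direction were in replication histone genes, such as hist1h2a7 at 11.64 (11.12 to 13.17), with 19354 reads in Dx-IONP and 9 in control. A candidate explanation for them, more RNA without a poly(A) tail in that library, is weighed under other observations. For histh1l3, with 0 reads in control, the level was at least 1728-fold higher. The tight junction gene cldn7b also had 0 reads in control and was at least 1185-fold higher. Why cldn7b had 0 reads was not tested, so its value is uncertain. At the other end, glud1a and HSPA9 had 0 reads in Dx-IONP and were at least 555-fold and 543-fold lower. Both serve basic metabolism or protein folding, why they had 0 reads was not tested, and their estimated counts are uncertain. CYP1A1, the enzyme induced through the aryl hydrocarbon receptor, was at 3.78 (3.72 to 3.85).

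Heart genes did not stand apart as a group in Dx-IONP against control. Cardiac muscle genes were lower for 7 of 16 and higher for 2 (median -0.59, -1.54 to 0.32, percentile 8.18). The natriuretic peptide gene nppa (ENSDARG00000052960), a marker of cardiac load, was at 3.24 CPM against 7.50 (log2 fold -1.20, -1.47 to -0.96), whereas its neighbour in function nppb was at 3.41 against 1.06 (1.65, 1.31 to 2.06). Another natriuretic peptide gene, nppal, was the farthest apart of the list, at 0.19 CPM against 2.2 (-3.37, -4.7 to -2.6). The cardiac light chain MYL7 was at 0.32 and the calcium pump atp2a2a at 0.20, neither of which passed the rule. The ventricular myosin heavy chain, listed as MYH7, was at -1.54, but its values ranged from 6.97 to 18.1 CPM between lanes of the control library, so its counts are uncertain. The Z-disc gene NEXN was at -3.12. Cardiac calcium handling genes (median 0.06) and cardiac transcription factors (median -0.57) did not stand apart. Of the latter list 4 of 15 members were higher and 5 lower, with ERBB2 at 3.08, TBX5 at 2.745, klf2b at 2.22 and spock2 at -2.055.

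**Figure D1:**
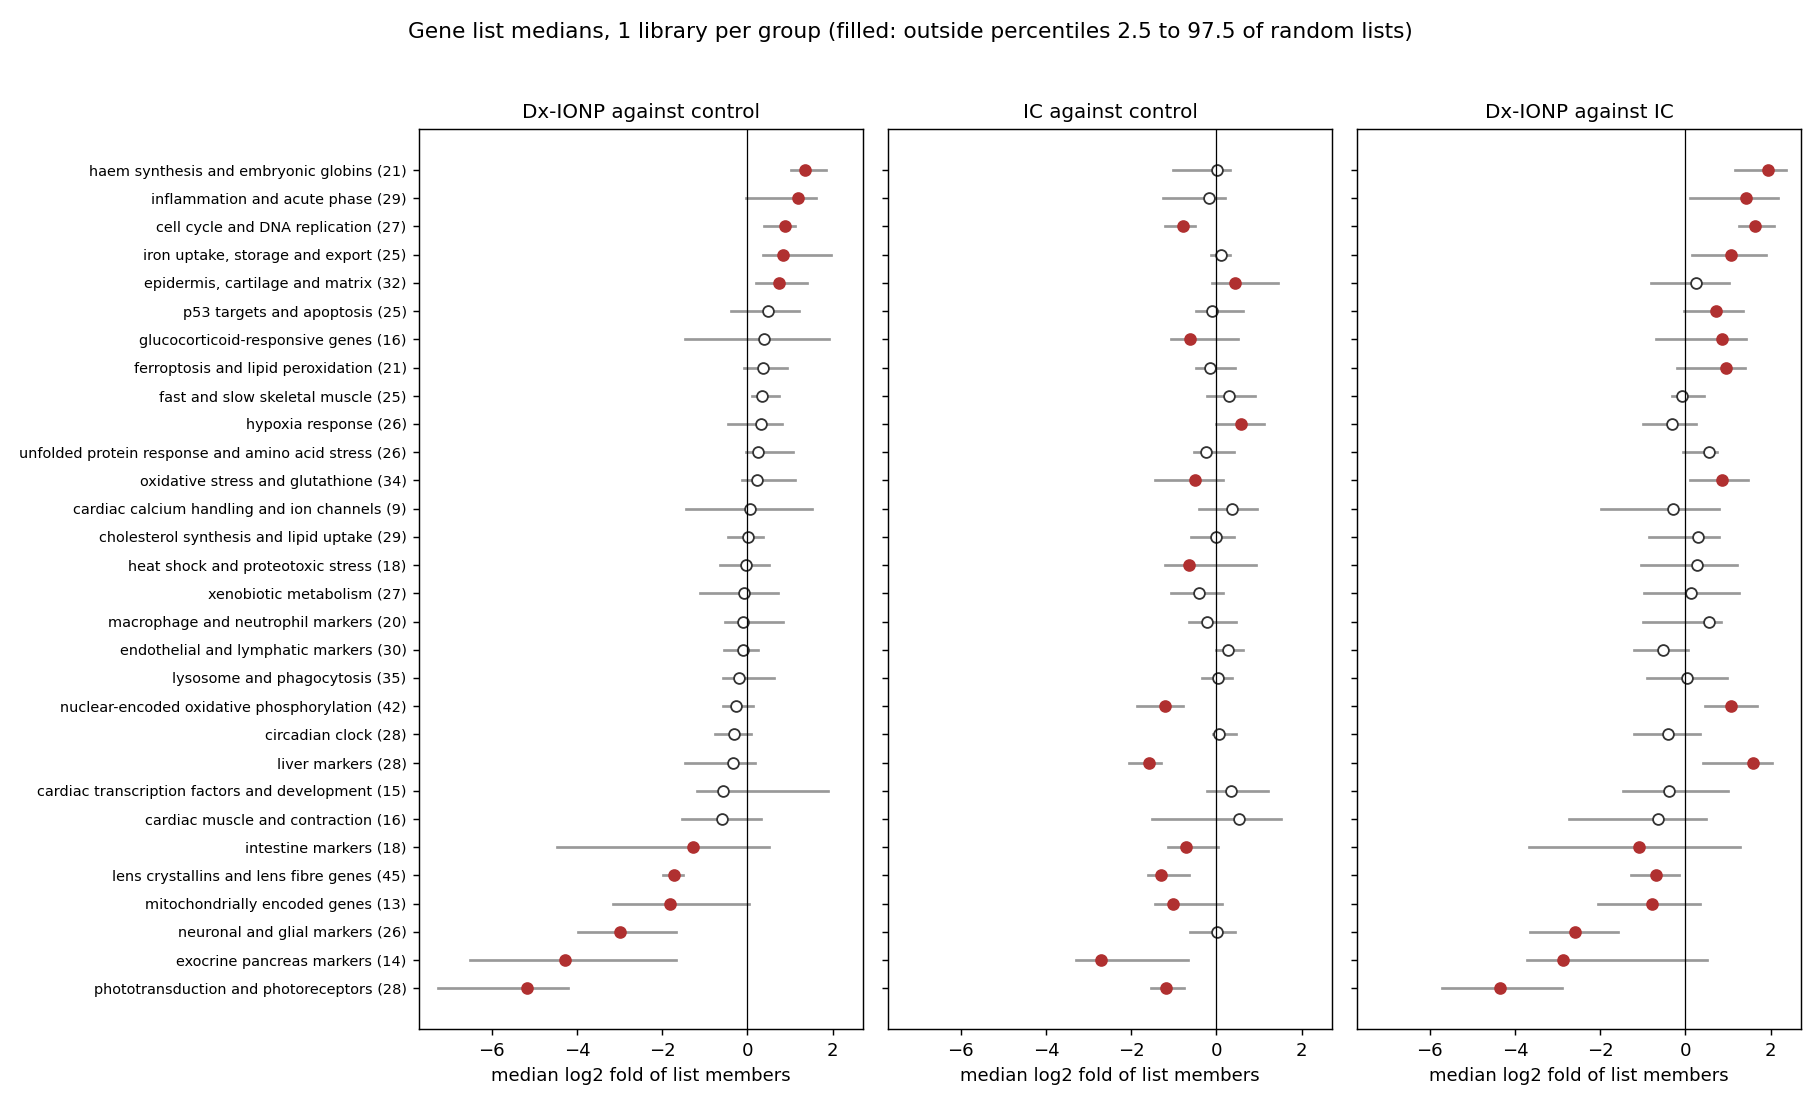
Median log2 fold (horizontal axis) of each of 30 gene lists, with the number of measured members in brackets, for the 3 comparisons of libraries. Bars are order-statistic 95% intervals over members and filled points stand apart from matched random lists. Photoreceptor genes lie lowest in Dx-IONP against control, at -5.18, and haem and globin genes highest, at 2.54-fold.

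The comparison of IC with control asked the same of the library that is by elimination the iron group. Genes made in liver and exocrine pancreas and small subunits of oxidative phosphorylation were lower in the IC library, and the natriuretic peptide genes nppa and nppb, single cartilage genes such as MATN3 and single hypoxia-response genes such as EGLN3 were higher. The lipoprotein gene apoa2 stood at 2024 CPM against 12370 in control, a log2 fold of -2.61 (-2.62 to -2.60). The natriuretic peptide gene nppa stood at 43.1 CPM against 7.50, 5.73-fold higher (5.28 to 6.27), and nppb at 5.76 against 1.06, 5.29-fold higher (4.30 to 6.88). Of 16807 genes, 4908 (29.2%) were at least 2-fold apart, 2377 higher and 2531 lower in IC.

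In IC against control, 13 of the 30 lists stood apart, and 11 to 14 under the alternatives. Liver markers were lower for 22 of 28 and higher for 0 (median -1.58, -2.05 to -1.30), with apoa1a at -2.49. Exocrine pancreas genes were lower for 11 of 14 (median -2.72, -3.30 to -0.67), with prss59.2 at -3.41. Nuclear-encoded oxidative phosphorylation genes were lower for 25 of 42 and higher for 2 (median -1.21, -1.86 to -0.78), among them the cytochrome oxidase subunits cox7b at -3.14 and cox6c at -2.96. In lists drawn up after the data were seen, small subunits were lower for 16 of 17 (median -2.03, -2.69 to -1.63), whereas large subunits were lower for 3 of 12 and higher for 1 (median -0.73, -1.09 to 0.37). Small ribosomal protein genes, also listed afterwards, were lower for 15 of 17 (median -3.12). Less recovery of short transcripts in that library is weighed under other observations. Mitochondrially encoded genes were lower for 7 of 13 (median -1.03, -1.44 to 0.13). Photoreceptor genes were lower for 17 of 28 (median -1.19, -1.53 to -0.77) and lens genes for 27 of 45, with 4 higher (median -1.29). Cell cycle genes were lower for 10 of 27 and higher for 0 (median -0.78), and intestine markers lower for 7 of 18 and higher for 2 (median -0.72), the latter not standing apart at 10 CPM. Oxidative stress genes (15 of 34 lower, 3 higher, median -0.51) and glucocorticoid-responsive genes (4 of 16 lower, median -0.61) also stood apart, the latter no longer in 6 of 16 alternatives. Heat shock genes did so as well, with 6 of 18 lower and 4 higher (median -0.64), but did not without lane 4 (-0.27) or among members with at least 10 CPM, where the median was 0.07. Its members went both ways, with hsp70.3 at -2.65 and hspb9 at 2.16.

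Of 26 hypoxia-response genes 9 were higher in the IC library and 0 lower, while 17 did not pass the rule (median 0.57, -0.02 to 1.12, percentile 99.2). Scaled to total reads, this list no longer stood apart (percentile 97.1). EGLN3, an oxygen sensor that hypoxia induces, was at 2.24 (2.14 to 2.35), NDRG1 at 1.80 and the carbonic anhydrase ca9 at 1.56. Epidermis, cartilage and matrix genes were higher for 11 of 32 and lower for 4 (median 0.44, -0.11 to 1.45), with the cartilage genes acana at 2.90, col9a3 at 2.82 and epyc at 2.62. The cartilage matrix genes MATN3, at 3.34, and acanb, at 3.14, were also among the 10 highest. The translation factor gene EIF1B was highest, at 5.13 (5.11 to 5.14), with 19330 CPM against 554. CLEC3A, a cartilage lectin gene, was at 4.47 and the collagen cross-linking enzyme gene LOXL4 at 3.52. Lowest were krt18a.1 and glud1a, with 0 reads in IC and levels at least 1123-fold and 594-fold lower, for reasons that were not tested, so both values are uncertain. The ribosomal protein gene RPL38 was at -4.49 (-4.60 to -4.40).

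Iron genes did not stand apart in IC (median 0.10, 3 of 25 higher and 2 lower). Within the list hamp was at -3.09 (-3.44 to -2.81) and fth1a at -1.43, while tfr1a was at 0.82 and did not pass the rule. The haem oxygenase gene HMOX1 was at -1.64 and CYP1A1 at -2.24. Cardiac muscle genes were higher for 5 of 16 and lower for 5 (median 0.52, -1.52 to 1.52, percentile 97.1) and did not stand apart. Endothelial markers did not either (median 0.27), although the junction gene cdh5 was 4.01-fold higher and the scavenger receptor gene stab2 at -2.67. The differences are between 1 library and another, and liver and pancreas genes were lower in the same library as hamp. Less recovery of short transcripts in the IC library, weighed under other observations, was not tested for the iron, liver, pancreas or cartilage genes.

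**Figure D2:**
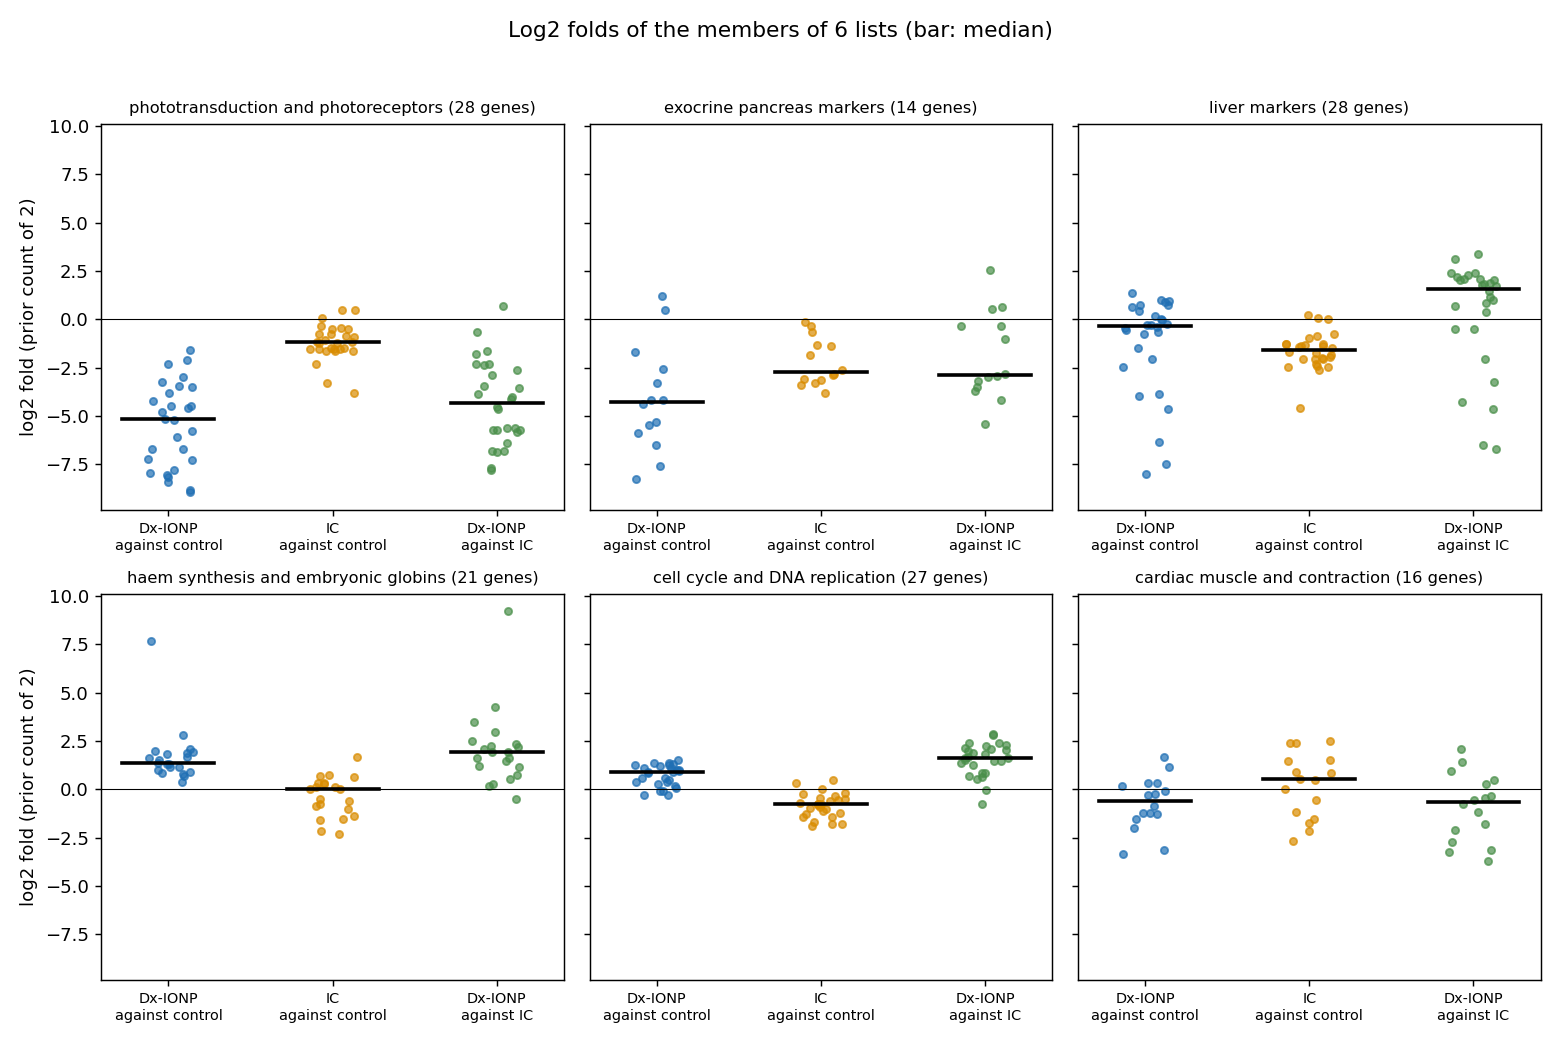
Log2 fold (vertical axis, prior count of 2) of every measured member of 6 lists in the 3 comparisons, each point a gene and each bar the list's median. All 28 photoreceptor genes lie below 0 in Dx-IONP against control, while the 16 cardiac muscle genes lie on both sides in each comparison.

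Setting Dx-IONP against IC asked how the coated particles differed from the iron group. Photoreceptor and neuronal genes were lower in Dx-IONP, and liver, globin, cell cycle and inflammation genes were higher. For liver genes this went with low values in IC (median -1.58 against control), since in Dx-IONP against control they had a median of -0.34. CYP1A1 was at 307 CPM against 4.70, a log2 fold of 6.02 (5.85 to 6.22), and nppa at 3.24 against 43.1 (-3.72, -3.98 to -3.50). HMOX1 was at 2.27 (2.17 to 2.38), tfr1a at 2.46 (2.35 to 2.57) and fth1a at 1.15 (1.13 to 1.17). A second ferritin gene, FTH1 (ENSDARG00000007975), was lower, at -2.34 (-2.50 to -2.18). HMOX1 stood at 86.7 CPM in Dx-IONP, 17.9 in IC and 55.9 in control, and fth1a at 1223, 553 and 1492. Both thus lay farther from control in IC, where they were low, than in Dx-IONP. Of 16807 genes, 8501 (50.6%) were at least 2-fold apart, 4046 higher and 4455 lower in Dx-IONP. Scaled to total reads alone, 2936 were higher and 5411 lower.

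Here 16 of the 30 lists stood apart, and 14 to 16 under the alternatives. Intestine markers no longer did in 5 of 16 alternatives, glucocorticoid-responsive genes in 3, p53 targets in 2 and iron genes in 1. Haem and globin genes were higher for 16 of 21 with 0 lower (median 1.93, 1.17 to 2.37) and cell cycle genes for 20 of 27 with 0 lower (median 1.63, 1.25 to 2.08), with PCNA, the sliding clamp of replication, at 5.28-fold. Liver markers were higher for 17 of 28 and lower for 6 (median 3.02-fold, log2 interval 0.40 to 2.03), with fabp10a at -6.73. Inflammation genes were higher for 17 of 29 and lower for 6 (median 1.41), with NOS2 at 4.89. Iron genes were higher for 13 of 25 and lower for 4 (median 1.08), or 12 of 24 and 4 without ftr83 (median 1.02, 0.12 to 1.89), and oxidative phosphorylation genes for 22 of 42, with 2 lower (median 1.07). In the size lists drawn up afterwards, small subunits were higher for 11 of 17 (median 1.55, percentile 100) and large subunits for 4 of 12 (median 0.32, -0.06 to 1.58, percentile 65.5). Oxidative stress genes were higher for 15 of 34 and lower for 6 (median 0.85), with the glutathione transferase gene gstp1.2 at 3.44. Ferroptosis genes (10 of 21 higher, 1 lower, median 0.95), glucocorticoid-responsive genes (8 of 16 higher, 2 lower, median 0.87) and p53 targets (11 of 25 higher, 6 lower, median 0.72) also stood apart. Against control, oxidative phosphorylation and oxidative stress genes stood apart only in IC, as lower (medians -1.21 and -0.51). In Dx-IONP against control their medians were -0.26 and 0.22. Ferroptosis genes and p53 targets stood apart in neither comparison with control. Lower in Dx-IONP were photoreceptor genes (26 of 28, 0 higher, median -4.35), neuronal and glial markers (20 of 26, 1 higher, median -2.59) and exocrine pancreas genes (8 of 14, 1 higher, median -2.88, -3.72 to 0.52). Lens genes (19 of 45 lower, 2 higher, median -0.69, -1.27 to -0.16) and mitochondrially encoded genes (5 of 13 lower, 2 higher, median -0.78, -2.05 to 0.34) stood apart with most members not past the rule or higher. With genes at 0 reads set to their bound, the pancreas median was -2.31. Intestine markers stood apart too (9 of 18 lower, 6 higher, median -1.08), but the median was 0.23 among members with at least 10 CPM. The myelin gene mbpa was at -6.62, VIL1 at -6.54 and OPN1SW at -9.68. The intermediate filament gene DES and the motor gene MYO10 had 0 reads in Dx-IONP, at least 250-fold and 174-fold lower, and the reason for their 0 reads was not tested either.

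The lists that stood apart in no comparison were cardiac muscle, cardiac calcium handling, cardiac transcription factors, skeletal muscle, unfolded protein response, circadian clock, endothelial and lymphatic, macrophage and neutrophil, xenobiotic metabolism, lysosome, and cholesterol synthesis. Their medians lay between -0.64 (cardiac muscle, Dx-IONP against IC) and 0.56 (macrophage and neutrophil, Dx-IONP against IC). Under alternatives cardiac muscle genes stood apart in IC against control in 4 of 16 (percentiles up to 98.6), xenobiotic genes there in 3, and endothelial markers in Dx-IONP against IC in 2.

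**Figure D3:**
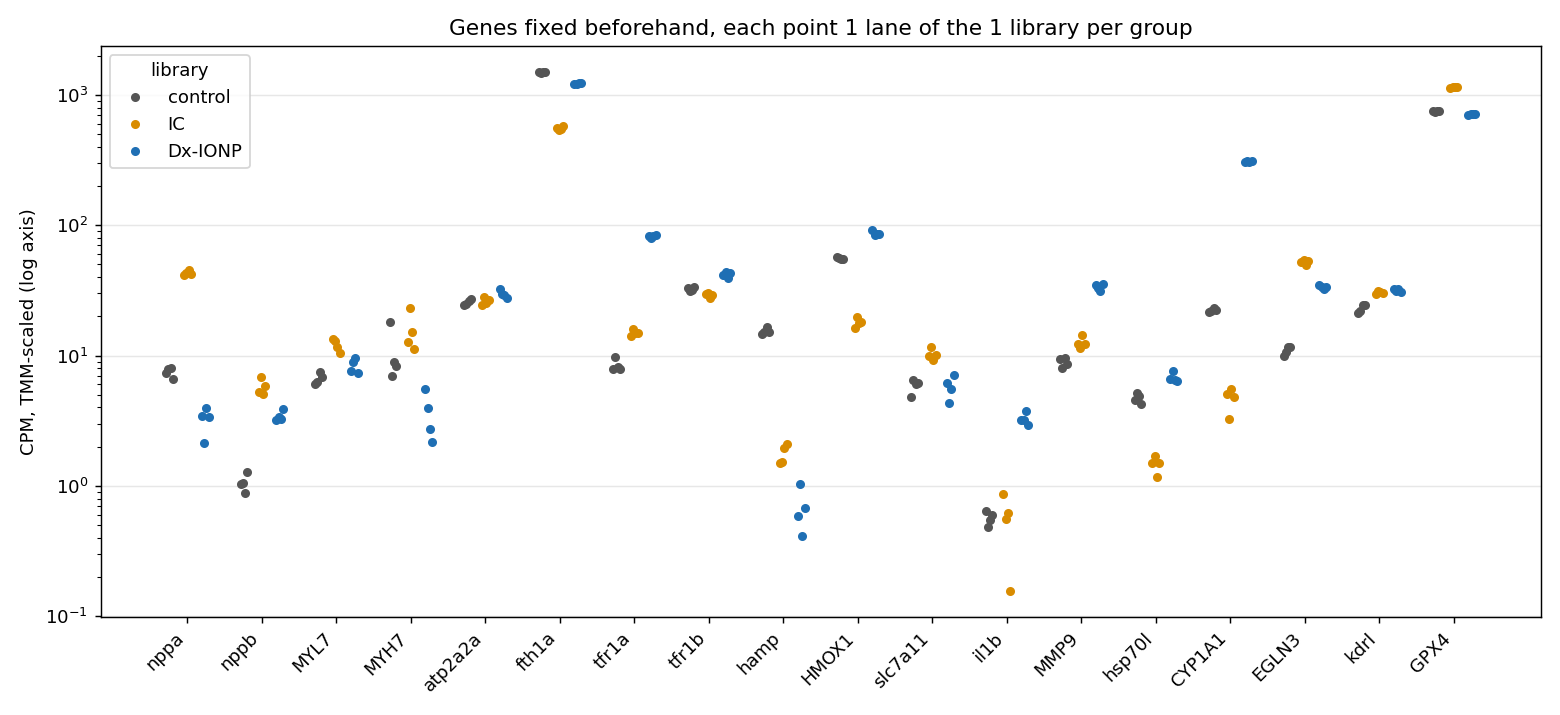
TMM-scaled CPM (vertical log axis) of 18 genes fixed beforehand, each point 1 lane and each colour the 1 library of a condition, so that points of a colour show lane noise and not replicates. CYP1A1 stands at 307 CPM in Dx-IONP, 22.3 in control and 4.70 in IC, and nppa highest in IC at 43.1.

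The Dx-IONP library stood farthest from the others, a distance that includes any difference between pools and between library preparations. It was at least 2-fold apart from both in the same direction for 5352 genes, 2171 higher and 3181 lower. The same count was 2468 for IC and 1764 for control. The 5 genes farthest from both were the histone genes hist1h2a7, hist1h2a4, hist1h2a9, histh1l3 and hist1h2a3. Reads shared by similar histone copies may be split unevenly between them, so the order of single copies is uncertain.

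Both comparisons against control shared genes such as hamp, lower in each, and EGLN3, higher in each, while nppa and CYP1A1 lay in opposite directions. In the same direction, 949 genes were higher and 815 lower in both, against 495.7 and 612.9 for independent lists of those sizes, and 569 genes lay in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 folds was 0.24 and their covariance 0.47. Libraries simulated without effects gave an r of 0.34 and a covariance of 0.004 from counting error alone, and 0.50 and 1.32 with the spread seen between the 3 libraries added. That simulation takes the whole spread between the 3 libraries, differences between conditions included, and its counts of 1343 higher and 1346 lower in both were above the observed ones. The single control library could not be split, and the excess over independent lists is not evidence of a shared difference.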

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

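Leaving out genes with 0 reads in any library, setting such genes to their bound, and leaving ftr83 out of the iron list were chosen after seeing the data; all other alternatives were chosen before. For lists that stood apart and named genes past the rule, the direction of most values did not depend on the processing. Of 140 recomputed counts of genes or lists, 121 stayed within 1.5 times the reported one. Of the list medians 1420 stayed within their interval over members, 19 moved outside it, and 4 of lists that stood apart changed sign. Sign changes were counted only for lists that stood apart, so medians of other lists among the 1420 or the 19 may have changed sign. Of the named genes' log2 folds 4135 stayed within their counting interval, 633 moved outside it and 0 that passed the rule changed sign. Leaving out each lane gave 7541 to 7565 genes for Dx-IONP against control, 4913 to 4954 for IC against control and 8484 to 8532 for Dx-IONP against IC. Lists standing apart numbered 10 to 11, 11 to 14 and 14 to 16 over all alternatives, and those lost were intestine, glucocorticoid, heat shock, hypoxia, p53 and iron lists. Without genes at 0 reads in any library the gene counts were 7410, 4837 and 8342. Scaling to total reads put the median gene at -0.35, -0.08 and -0.28 on the log2 scale in that order, and without the abundant tissue lists at -0.39, -0.11 and -0.27, so directions of lists are relative to it. With a filter of at least 10 CPM, which tests fewer genes, 5018 genes remained apart for Dx-IONP against control, 3514 for Dx-IONP from both other libraries and 1126 in the overlap. Under that filter, as with only list members of at least 10 CPM, the heat shock median in IC against control was 0.067 and the intestine median in Dx-IONP against IC 0.23, because low members left the list. At 1.5-fold, 9070 genes were apart for IC against control and 4017 in the overlap. At 4-fold the counts were 3237 for Dx-IONP against control, 822 for IC against control, 3504 for Dx-IONP against IC, 2181 for Dx-IONP from both and 218 in the overlap. Lanes entered as samples gave, in edgeR, 14706, 13643 and 14795 genes at an adjusted p under 0.05, and in DESeq2 14297, 13120 and 14462, since lanes carry no spread between pools. With the lane as a replicate block the edgeR counts were 14655, 13574 and 14758. Lanes of the same number did not vary together in gene levels (correlations across genes of -0.04 to 0.05). Their read totals did, with lane 3 the deepest and lane 2 the shallowest in each library. Whether the libraries shared physical lanes is not decided by these values. Counting error kept 1, 30 and 8 genes of at least 2-fold from passing the rule in the order above, so depth limited few of the counts, and no alternative replaces replicate pools.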

Other observations

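The lists of histones, ribosomal proteins, oxidative phosphorylation subunits by size, hatching gland and early embryo genes were written after the data were seen, as were all tests below except those on early embryo genes and on oxidative phosphorylation subunits of different size.

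Hatching gland proteases, enzymes that dissolve the egg envelope, were higher in the Dx-IONP library. Against control ctslb.4 was at 5.92 and ctslb at 7.83, with 38.9 CPM against 0.14, while he1.3 had 109 reads in Dx-IONP and 0 in both other libraries. In IC against control, 2 of the 3 were higher, ctslb.4 at 3.58 and ctslb at 2.94. Ribosomal protein genes were lower in the IC library, 15 of 17 small ones (median -3.12, -3.74 to -2.06) and 9 of 12 large ones (median -1.21, -1.63 to -0.33). Replication-independent histone genes had a median of -0.35 (-1.92 to 0.21) in Dx-IONP against control. Between 5 and 45 genes per library had 0 reads there and at least 10 CPM elsewhere: 20 in control, 45 in IC and 5 in Dx-IONP.

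The low photoreceptor genes of the Dx-IONP library were weighed first. A few abundant genes taking the counts are argued against, since without the 100 most abundant genes the photoreceptor median was -5.35 (-7.43 to -4.36). An equal loss of all eye tissue is argued against by the lens genes. Their median of -1.72 (-1.98 to -1.51) lay above the photoreceptor interval of -7.25 to -4.21. Lens genes were lower as well (37 of 45, with 0 higher), so less eye tissue as a part of the pattern stays open, as does a loss within the retina. A younger stage of that pool, which could also go with the high hbbe3 and hatching gland genes, stays open. It stays open too for the low exocrine pancreas genes (12 of 14, 1 higher) and neuronal and glial markers (23 of 26, 1 higher), while liver markers did not stand apart. Segmentation and early embryo genes had a median of -0.093 (-2.46 to 0.66, 15 measured), with members on both sides. As genes of early embryos, they could not show a delay within larval stages. The labels give the same age for all pools. A difference in stage was not weighed for the IC library. In it photoreceptor genes were lower than in control (17 of 28, 0 higher) and 2 of the 3 hatching gland proteases higher. Exposure, pool and library preparation cannot be told apart with 1 of each per condition, so an effect of the particles on development was not tested by itself.

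The replication-dependent histone genes of the Dx-IONP library had a median log2 fold of 10.25 (9.50 to 11.04) over 16 genes, 14 of them higher and 1 lower. Both exceptions were abundant in control: histh1l1 at 0.82, with 61175 control reads, and hist2h2l at -1.55. Most of the 16 are members of the hist1h2a family. Reads shared by similar copies are split by likelihood, so these genes may not be separate measurements and the interval over them may be too narrow. More dividing cells alone are argued against by the cell cycle median of 0.89, whose upper bound of 1.11 lay far below. These mRNAs mostly lack a poly(A) tail, so a candidate explanation is that more RNA without a tail entered that library. MT-ND6, a mitochondrial mRNA known to lack a tail, was at 2.46 while the 12 other mitochondrially encoded genes lay between -3.48 and 0.16. That order is as the explanation needs. The fold of MT-ND6 was far below the histone median of 10.25, so the size of the histone difference is not accounted for. MT-ND6 is also 1 gene, and reads from the opposite strand cannot be excluded. Whether this library was prepared apart was not given in the sources used here.

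The low ribosomal protein genes of the IC library may reflect less recovery of short transcripts. The median of small minus large ribosomal proteins was -1.91. That of small minus large oxidative phosphorylation subunits was -1.29, with intervals that did not overlap (-2.69 to -1.63 against -1.09 to 0.37). The latter test was written before its result was seen. Its lists were written after the data were seen and hold genes named above as low, such as cox7b and cox6c, so it is no independent check. Transcript lengths were not used here, so size was taken from the proteins. Single members went against the pattern in IC against control. Of the small ones RPL31 was at 0.49 and atp5mc3b at 0.12, and of the large ones RPL13A was at -3.31 and RPL13 at -2.78. Whether short transcripts account for the whole pattern stays open, as does an effect of the exposure on these genes.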
